A study of Mus musculus with 8 samples.

How the data were processed

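Total RNA of 8 cultures of mouse bone marrow-derived macrophages was sequenced as paired-end reads on an Illumina NovaSeq instrument from libraries made with the VAHTS Universal V6 kit, per the labels' protocols. The labels give 24 h of IL-4 for all 8 and divide them by genotype into 4 CKO and 4 FLOX libraries. The tissue label says BMDM, while the text of the extraction protocol speaks of islets, and a list of islet markers was therefore included among the gene lists. Per the submitters' processing notes reads were aligned with HISAT2 2.0.5 to mm10 and counted with HTSeq. The version of HTSeq, the gene annotation and the strand setting are not given in the sources used here. Overlapping and antisense genes are thus uncertain, since reads of both partners cannot be told apart without strand.

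The deposited values are whole-number counts of read pairs per gene symbol, not normalised, in 1 file per library with 24421 gene symbols. A table of the whole series holds the same values in its columns (0 columns had no sample), but 27 of its gene names had turned into dates and 4 rows then shared a name, so the counts per library were taken from the single files. HTSeq's 5 classes of unassigned read pairs were kept out of library sizes and tests. They hold 6.52% to 9.60% of pairs in no gene, 12.2% to 18.0% of low mapping quality, 1.56% to 1.69% ambiguous, 0.819% to 1.19% unaligned and 5.03% to 6.01% with more than 1 alignment. Pairs assigned to genes came to 66.3% to 71.7% of all, or 11764855 to 18939948 per library. Multiply aligned pairs were not assigned, so near-identical genes lose reads. The 20 most abundant genes took 9.88% to 11.1% of the assigned counts in CKO and 12.6% to 13.7% in FLOX.

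Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 11519. Libraries were scaled by TMM factors, dispersions were estimated with robust settings, and CKO was compared with FLOX by the quasi-likelihood F test with 6 residual degrees of freedom before moderation. P-values were adjusted by Benjamini-Hochberg over all tested genes and called at 0.05. The standard error of a log2 fold change is its size divided by the square root of F, and 95% intervals use 6 degrees of freedom. The biological coefficient of variation was 8.77%. CPM values, and sums of them over all members of a list in the files, use TMM-scaled library sizes, and means are given with the SD over 4 libraries. Intervals and the limit of 3 counts that a count of 0 allows cover counting error only where they rest on single counts. No pair of libraries within a group differed by as little as sampling noise (chi-square per degree of freedom 2.45 to 27.9 over the tested genes), so all 8 were used as separate libraries.

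A set of 35 gene lists was fixed before the data were examined, and 28 with 5 or more tested members were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the 28 lists. Beside it stand camera with a correlation estimated for each list, under which 0 lists were called, against 13 with the preset one, and fry, which asks whether a list's genes move one way on balance and called 17. The rule for named genes was also fixed before the data were examined: Opa1 and Lyz2, the 12 largest rises and 12 largest falls among called genes with a mean log2 CPM of at least 1 and no overlap of ranges, up to 4 genes of smallest p in each list, and 18 genes always given. Outside this rule stand Csf1r, Dmwd, its neighbours Sympk, Fbxo46, Rsph6a and Six5, and Dusp6, Epha2, Id3, Ly6c2, Smad6 and Spry2. Gene positions and transcript GC content and length were taken from GENCODE M21 on GRCm38, the same assembly as mm10; 23336 symbols had a position, and 96.4% of the tested genes had a length.

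On simulated counts drawn from the means, dispersions and library sizes of this comparison (11446 genes), the test recovered 3 of 50 genes changed 1.2-fold, 38 of 47 changed 1.5-fold, 46 of 50 changed 2-fold and 50 of 50 changed 4-fold, and called 10 of 11249 unchanged genes. Few genes were changed there, which makes the Benjamini-Hochberg cut stricter than in the real comparison with its 5231 calls. Recovery of small changes in the real comparison is thus not measured by it. In simulated lists, 1 shifted list was called and 0 of the others. Genes were drawn independently there, whereas the correlation estimated within real lists reached 0.859. The simulation thus cannot tell how often lists are called falsely in these data.

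Alternatives were RLE and upper-quartile factors, no filter and a filter of at least 1 CPM in 4 libraries, DESeq2 1.42.0, limma-voom, each library left out in turn, the replicate number as a block, the 20 most abundant genes removed, a GC offset, a log2 fold change above 1 for calls, and both other list tests. A term for sex was not run because all 8 libraries express Y-linked genes, and removal of mitochondrially encoded genes changes nothing since 0 were counted. Chosen after the data were seen were an offset for GC content and length, the share of pairs in no gene as a covariate, and leaving out CKO replicate 2 and FLOX replicate 6 together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.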

Results

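Bone marrow-derived macrophages (BMDM), which are macrophages grown in culture from bone marrow, were profiled by RNA sequencing 24 h after stimulation with interleukin 4 (IL-4), the cytokine that drives alternative activation. In 4 libraries the cells came from OPA1f/f mice carrying the Lyz2-Cre driver, which expresses Cre recombinase in myeloid cells from the Lyz2 locus (CKO, replicates 2, 6, 7 and 8). In the other 4 libraries the cells came from OPA1f/f mice without the driver (FLOX, replicates 3, 4, 6 and 7). The study asked how macrophage transcription after IL-4 depends on OPA1, a dynamin-like GTPase of the inner mitochondrial membrane that acts in fusion and cristae shape. No unstimulated library was part of the comparison, so every value describes genotype under IL-4. Between 11764855 (CKO replicate 2) and 18939948 (FLOX replicate 6) read pairs per library were assigned to genes. The labels do not say whether the libraries of a group come from separate mice, and p-values therefore measure only the spread between these libraries.

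The targeted gene was barely lower at the level of the whole gene, whereas the driver gene was far lower. Opa1 (ENSMUSG00000038084, chromosome 16, 29579334 to 29654884, mm10) stood at 100.1 ± 4.42 CPM (counts scaled to library size) in CKO and 114 ± 11.7 CPM in FLOX (SD, n = 4 each). Its log2 fold change was -0.19 (SE 0.07, edgeR adjusted p = 0.0544), or 87.7% of FLOX with a 95% interval from 77.3% to 99.5%. The call depended on the processing: 5 of 20 alternatives put it past the threshold, and adjusted p ran from 0.000869 to 0.2 over them. Among these were the fits without FLOX replicate 3 (log2 fold change -0.23, edgeR adjusted p = 0.0182) and without FLOX replicate 6 (-0.21, edgeR adjusted p = 0.0496). The counts are gene totals, so they do not resolve the exons flanked by loxP sites, and a transcript lacking those exons is still counted as Opa1. Lyz2 (ENSMUSG00000069516, chromosome 10, 117277331 to 117282321), which encodes lysozyme 2 and holds the Cre insertion, stood at 2030 ± 251 CPM in CKO and 7439 ± 597 CPM in FLOX (SD, n = 4 each). That is 27.3% of FLOX (log2 fold change -1.87, SE 0.10, edgeR adjusted p = 1.05e-07), with no overlap between the libraries of the groups. Every library thus matched its label by the driver gene, and none could be checked by the deleted part of Opa1.

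**Figure D1:**
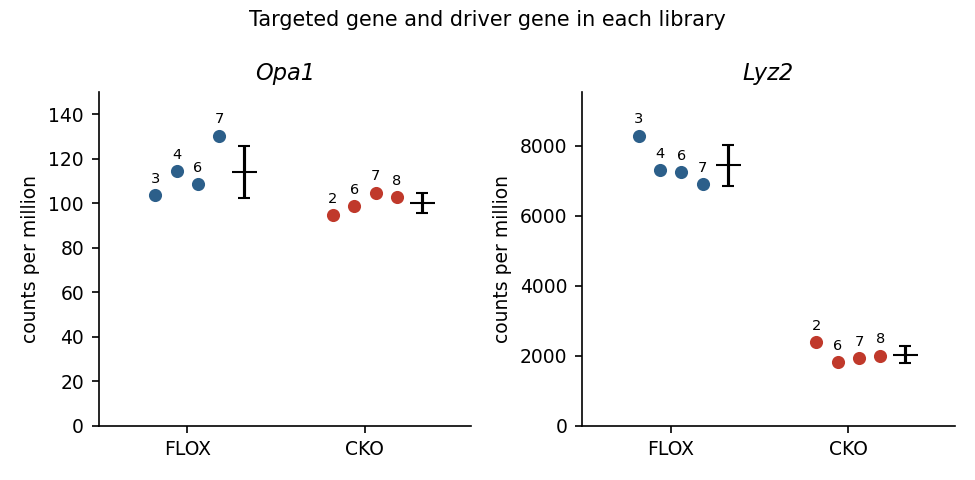
CPM of Opa1 (left) and Lyz2 (right) in each library, with the replicate number above each point; the black mark and bar show the mean and SD of 4 libraries. The Opa1 ranges of CKO and FLOX overlap, while the 4 CKO libraries lie at 1809 to 2387 CPM of Lyz2 and the 4 FLOX libraries at 6906 to 8294 CPM.

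The main difference between the libraries followed the labelled groups. CKO also carries the Cre driver, so Opa1 deletion, the driver and any unlabelled batch that follows the groups cannot be told apart. Of 11519 genes tested, 5231 (45.4%) passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 2739 higher and 2492 lower in CKO. Counts of list members that rose or fell are to be read against these shares of all tested genes. Most changes were small: 538 of the higher and 135 of the lower genes changed by more than 2-fold. The CPM ranges of the groups did not overlap for 4918 genes (42.7%, where chance gives 2.86%). The first principal component held 70.2% of the variance and parted the groups. The second held 12.7% and parted FLOX replicates 3 and 6 from FLOX replicates 4 and 7. CKO replicate 2 was the CKO library nearest to FLOX for 61.1% of the called genes, and FLOX replicate 6 the FLOX library nearest to CKO for 40.4%, where an even spread would give 25%. Without both libraries 4857 genes were called.

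The genes with the largest rises included regulators of growth signalling and of the cell cycle. Cyclin D1 (Ccnd1), which drives entry into the cell cycle, rose from 29.7 ± 5.94 CPM in FLOX to 358 ± 62.6 CPM in CKO (SD, n = 4 each; log2 fold change 3.58, SE 0.17, edgeR adjusted p = 1.95e-07). Cyclin D2 (Ccnd2) rose by 3.52. Id1, an inhibitor of basic helix-loop-helix transcription factors, rose from 0.469 ± 0.194 to 15.7 ± 4.59 CPM (log2 fold change 5.06, SE 0.32, edgeR adjusted p = 6.6e-07). Etv5, an ETS transcription factor, rose by 3.06 and Spred2, an inhibitor of the RAS and ERK pathway, by 3.31 on the log2 scale. The other 7 rises that the rule for named genes selected were Dmpk (4.02, or 4.83 without FLOX replicate 6), Ehd2 (3.86), Abtb2 (3.33), Pydc4 (3.22), Ly6a (3.08), Cd276 (3.03) and Tox2 (2.94). Pydc4 belongs to a family of near-identical genes, and its counts may include reads of its relatives. Ehd2, Abtb2, Cd276 and Dmpk averaged 0.661, 0.814, 1.01 and 1.02 CPM in FLOX, so their fold changes rest on few FLOX counts.

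The largest falls included genes of alternative activation and lipid handling. Chil3 (Ym1), a chitinase-like marker of IL-4 stimulated mouse macrophages, fell from 145 ± 24.1 to 39.0 ± 5.00 CPM (SD, n = 4 each; log2 fold change -1.90, SE 0.13, edgeR adjusted p = 8.68e-07). Its near-identical neighbour Chil4 had a log2 fold change of -2.20, and reads may be split between the 2 genes. Fabp4, a fatty acid binding protein, fell from 156 ± 20.5 to 44.8 ± 3.38 CPM (log2 fold change -1.80, SE 0.09, edgeR adjusted p = 1.17e-07). The chemokine Ccl8 changed by -2.77, Bex1 by -3.04, adiponectin (Adipoq) by -2.34, Fxyd2 by -1.97 and the deiodinase Dio2 by -1.87. Pkdcc (-1.80), the betaine transporter Slc6a12 (-1.71), the scavenger receptor Stab2 (-1.68) and Lyz2 completed the 12. Bex1, Ccl8, Pkdcc, Stab2 and Adipoq were below 3 CPM on average in CKO. Adipoq also belongs to the list of stromal and endothelial markers, and which cells its reads came from was not tested.

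**Figure D2:**
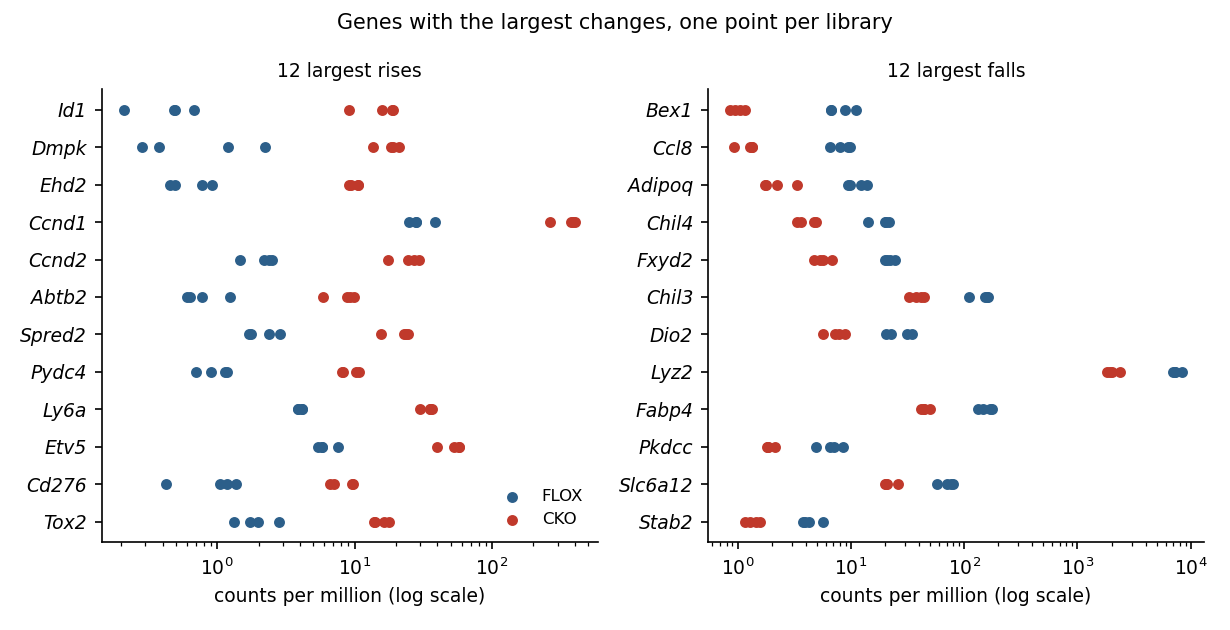
CPM on a log scale for the 12 largest rises (left) and the 12 largest falls (right), one point per library. The CKO and FLOX libraries do not overlap for any of these genes; Ccnd1 and Lyz2 are the most abundant of each set.

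Interferon-stimulated genes rose together. Of 65 tested members of the type I interferon list, 60 rose and none fell (62 and 1 adjusted over the list alone), with a median log2 fold change of 0.79. Irf7, a transcription factor that amplifies the interferon response, rose from 62.5 ± 4.22 to 213 ± 9.41 CPM (SD, n = 4 each; log2 fold change 1.77, SE 0.07, edgeR adjusted p = 1.4e-08). Ifi44 rose by 2.33, Ms4a4c by 1.69 and the chemokine Cxcl10 by 1.49 (2.08 without FLOX replicate 6), and the ubiquitin-like modifier Isg15 from 17.6 ± 3.89 to 50.1 ± 1.81 CPM. The mean log2 CPM of 4 tested monocyte markers was higher in all CKO libraries (4.80 ± 0.03 against 4.25 ± 0.14, SD, n = 4 each), whereas the sum of the 9 monocyte markers in the files was lower in all (984 to 1119.8 against 1191 to 1589 CPM), S100a4 being the most abundant named member. The type I interferon list was called higher with a camera adjusted p of 1.01e-24, but the call was lost with an estimated correlation (adjusted p = 0.292). Ifnb1 itself had 1 count in 1 CKO library and 0 in the others, too few to test.

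Sensors of cytosolic DNA moved in part. Of 39 tested members, 16 rose and 6 fell (17 and 6 adjusted over the list alone), with a median of 0.07 and a camera adjusted p of 0.0486 (adjusted p = 0.545 with an estimated correlation). The gene of the DNA sensor cGAS (Mb21d1) rose from 18 ± 1.54 to 41.8 ± 4.97 CPM (SD, n = 4 each; log2 fold change 1.22, SE 0.10, edgeR adjusted p = 1.63e-06), whereas that of its partner STING (Tmem173) fell by 0.27 on the log2 scale (SE 0.07, edgeR adjusted p = 0.00865). Mnda (1.22) and Ifi204 (0.76), both of the interferon-inducible p200 family with close relatives, also rose. The call of this list ended in 12 of 20 other alternatives (adjusted p between 0.05 and 0.102 there), among them the fits without CKO replicate 2 (0.0613), 6 (0.0597) or 7 (0.0621) and without FLOX replicate 4 (0.063), 6 (0.068) or 7 (0.0855), and 5 of the 35 splits of the libraries gave a camera p as small. Here and below such counts include the real split. Splits that keep most libraries of a genotype together also still carry part of its effect.

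Cell cycle genes were higher in CKO almost without exception. Of 41 tested members of the proliferation list 40 rose and none fell, also when adjusted over the list alone, with a median log2 fold change of 0.97. The replication licensing factor Cdc6 rose from 5.46 ± 1.17 to 26.5 ± 2.84 CPM (SD, n = 4 each; log2 fold change 2.26, SE 0.14, edgeR adjusted p = 2.23e-07), and the helicase subunit Mcm2 from 29.6 ± 5.01 to 91.4 ± 4.97 CPM (log2 fold change 1.62). The camera adjusted p was 1.01e-21 (adjusted p = 0.318 with an estimated correlation). Among 29 genes of p53 signalling and apoptosis 15 rose and 6 fell (16 and 7 adjusted over the list alone), with a median of 0.20, a camera adjusted p of 0.0226 and an adjusted p of 0.318 with an estimated correlation. Of the 35 splits of the libraries 2 gave a camera p as small, and the replicate number as a block ended the call (camera adjusted p = 0.063). Members of this list with the smallest p included Bcl2 (1.91) and Bcl2l1 (1.24), which encode inhibitors of apoptosis, and the kinase gene Plk3 (1.44). Neutrophil and precursor markers also differed with genotype, but by sign according to the measure. Their mean log2 CPM was higher in CKO (1.84 ± 0.31 against 0.97 ± 0.15, SD, n = 4 each), resting on genes of a few CPM, and their sum was lower in all CKO libraries (123 to 154 against 219 to 316 CPM), resting on Csf3r.

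Genes of lysosomes and of cholesterol efflux were lower in CKO. Of 40 lysosome and autophagy genes 34 fell and none rose (37 and 0 adjusted over the list alone), with a median log2 fold change of -0.44. They included the collagen-degrading cathepsin K (Ctsk, -1.30), Gabarapl1 (-0.87), the mitophagy receptor Bnip3l (-0.82) and Tfeb (-0.83), a transcription factor that drives lysosome genes, which fell from 85.3 ± 6.36 to 48.0 ± 3.09 CPM (SD, n = 4 each; SE 0.07, edgeR adjusted p = 2.36e-06). The camera adjusted p was 1.31e-12 (adjusted p = 0.318 with an estimated correlation). Of 13 genes of LXR targets and cholesterol efflux 11 fell and 1 rose (12 and 1 adjusted over the list alone), with a median of -0.57. The phospholipid transfer protein Pltp (-1.02), Mylip (-0.72) and the sterol exporter Abcg1 (-0.71) fell. Msr1, a scavenger receptor that takes up modified lipoprotein, was the exception and rose from 66.4 ± 5.66 to 267 ± 33.6 CPM (SD, n = 4 each; log2 fold change 2.01). The camera adjusted p of the cholesterol efflux list was 0.000252 (adjusted p = 0.318 with an estimated correlation).

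The IL-4 response genes did not move as a block. Of 40 tested members 20 fell and 9 rose (20 and 10 adjusted over the list alone), with a median of -0.18. Arginase 1 (Arg1), which converts arginine to ornithine, rose from 232 ± 14.4 to 594 ± 116 CPM (SD, n = 4 each; log2 fold change 1.36, SE 0.12, edgeR adjusted p = 5.18e-06), and so did Cdh1 (2.84) and transglutaminase 2 (Tgm2, 1.04). Retnla (Fizz1) fell from 646 ± 119 to 301 ± 49.5 CPM (log2 fold change -1.10, edgeR adjusted p = 7.16e-05), as did Chil3 and the proton pump subunit Atp6v0d2 (906 ± 93.7 to 394 ± 37.6 CPM). The mannose receptor Mrc1 was at 2310 ± 122 and 2016 ± 204 CPM (log2 fold change 0.20, edgeR adjusted p = 0.0611), and 7 of 20 alternatives called it, among them the fits without CKO replicate 2 (adjusted p = 0.0282) and without FLOX replicate 7 (0.0197). The list was called lower with a camera adjusted p of 0.0475 (adjusted p = 0.626 with an estimated correlation), and the call ended in 8 of 20 other alternatives, among them fry (adjusted p = 0.0624) and the fits without CKO replicate 2 (0.0504) or 6 (0.0557) and without FLOX replicate 4 (0.063) or 7 (0.0571). Of the 35 splits of the libraries 12 gave a camera p as small. Of 24 tested genes of macrophage identity 12 fell and 4 rose (13 and 4 adjusted over the list alone; median -0.25, camera adjusted p = 0.0695, not called, although 5 of 20 other alternatives called it, with 0.0219 without CKO replicate 2), and the sum of the list was lower in all CKO libraries (13386 to 15521 against 18213 to 19349 CPM). Gpnmb (-0.71) and Cebpa (-0.61) fell and the Fc receptor Fcgr1 (1.04) and Siglec1 (1.11), both also interferon-inducible, rose. Csf1r, the receptor for the growth factor of macrophages, named here after its value was seen, changed by -0.42.

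Amino acid and stress response genes downstream of ATF4 were higher in CKO. Of 44 tested members of the integrated stress response list 33 rose and 5 fell (34 and 5 adjusted over the list alone), with a median of 0.60 and a camera adjusted p of 1.96e-09 (adjusted p = 0.318 with an estimated correlation). The pseudokinase Trib3 rose from 9.74 ± 1.99 to 45.9 ± 3.17 CPM (SD, n = 4 each; log2 fold change 2.22, SE 0.12, edgeR adjusted p = 1.17e-07). The amino acid transporters Slc1a4 (1.85) and Slc7a1 (1.58) and the proline synthesis enzyme Aldh18a1 (1.10) also rose. The transcription factors at the head of this response rose less, Atf4 by 0.36 and Ddit3 by 0.32, and the secreted factor Gdf15 by 0.63. Fgf21 had 0 counts in every library. In contrast, 7 of 21 tested endoplasmic reticulum stress genes fell and none rose, also when adjusted over the list alone (median -0.07, camera adjusted p = 0.0475, adjusted p = 0.35 with an estimated correlation), among them Dnajb9 (-0.45) and Xbp1 (-0.32). That call ended in 9 of 20 other alternatives, among them the fits without CKO replicate 2 (0.0613), 6 (0.0597) or 7 (0.0911) and without FLOX replicate 3 (0.0691) or 6 (0.068), and 4 of the 35 splits gave a camera p as small.

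Metabolic genes shifted by small amounts. Of 36 genes of glycolysis and the hypoxia response 19 rose and 3 fell, also when adjusted over the list alone (median 0.28, camera adjusted p = 4e-04, adjusted p = 0.318 with an estimated correlation). The glucose transporter Slc2a1 rose from 29.9 ± 1.42 to 51.3 ± 2.95 CPM (SD, n = 4 each; log2 fold change 0.78), the phosphofructokinase Pfkl by 0.94 and the collagen hydroxylase P4ha2 by 1.34. Of 41 nuclear genes of respiratory complexes II to V 17 fell and none rose, also when adjusted over the list alone (median -0.20, camera adjusted p = 4e-04, adjusted p = 0.654 with an estimated correlation, fry adjusted p = 0.113). Their sum was 8339 and 7791 CPM in FLOX replicates 3 and 6 but 6963 and 6688 CPM in FLOX replicates 4 and 7, against 6229 to 6901 CPM in CKO. Uqcrh of complex III fell from 163 ± 24.2 to 99.1 ± 4.66 CPM (log2 fold change -0.72) and Sdha of complex II by 0.26 on the log2 scale. For complex I, 6 of 43 genes fell and none rose (3 and 0 adjusted over the list alone; median -0.14, camera adjusted p = 0.0615, not called, although 4 of 20 other alternatives called it, with 0.00721 without FLOX replicate 4 and 0.00293 without FLOX replicate 7), with Ndufa1 at -0.40. The share of complex I genes that fell was smaller than over all tested genes (2492 of 11519). The complex I sum was 2625 and 2481 CPM in FLOX replicates 3 and 6, and in FLOX replicates 4 and 7 (2109 and 2058 CPM) it lay within the CKO range (1991 to 2204 CPM). Of the 35 splits of the libraries, 18 for complexes II to V and 22 for complex I gave a camera p as small.

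Lipid genes went both ways. Of 32 genes of fatty acid uptake and oxidation 20 fell and 2 rose, also when adjusted over the list alone (median -0.23, camera adjusted p = 0.00192, adjusted p = 0.545 with an estimated correlation). Fabp5 changed by -1.21 and the triglyceride lipase Pnpla2 by -0.68, whereas lipoprotein lipase (Lpl) rose from 2018 ± 163 to 3643 ± 92.8 CPM (SD, n = 4 each; log2 fold change 0.85). The sum of the list went the other way from its median and was higher in all CKO libraries (8463 to 8659 against 7272.5 to 7765 CPM), Lpl being the most abundant named member. Of 32 genes of cholesterol and fatty acid synthesis 17 rose and 3 fell (18 and 3 adjusted over the list alone; median 0.23, camera adjusted p = 0.00259, adjusted p = 0.626 with an estimated correlation). Elovl6 (1.44), Hsd17b7 (1.11) and fatty acid synthase (Fasn, 0.73) rose, and the desaturase Scd1 changed by -1.17. Of the 35 splits, 7 gave as small a camera p for the first list, 13 for the second and 5 for glycolysis.

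Mitochondrial lists other than the respiratory chain were not called by camera with the preset correlation, and fry called 2 of them. Of 35 genes of mitochondrial dynamics and cristae 9 rose and 7 fell, also when adjusted over the list alone, with Mtfr2 (from 15.7 ± 1.92 to 36.0 ± 2.12 CPM; SD, n = 4 each) and Atad3a (log2 fold change 0.53) higher. The median was -0.01, the mean 0.05 and the camera test pointed up (adjusted p = 0.757). The shares that rose and fell lay near those over all tested genes (2739 and 2492 of 11519). Of 28 genes of mitochondrial DNA maintenance and expression 8 rose and 1 fell (7 and 1 adjusted over the list alone; median 0.05, camera adjusted p = 0.368, fry adjusted p = 0.0245; sum 863 to 902 CPM in CKO and 841 to 861 CPM in FLOX), with Pnpt1 at 0.48. Tfam, which packages mitochondrial DNA, was at 34.9 ± 0.903 and 30.9 ± 1.42 CPM (SD, n = 4 each; log2 fold change 0.17, edgeR adjusted p = 0.038), a call that ended in 10 of 20 alternatives (adjusted p 0.0237 to 0.427), among them the fits without CKO replicate 6 (0.0781) or 8 (0.0504) and without FLOX replicate 3 (0.0722), 4 (0.1) or 6 (0.0607). Of 19 mitochondrial chaperone, protease and import genes 10 rose and 1 fell, also when adjusted over the list alone (median 0.15, camera adjusted p = 0.0615, fry adjusted p = 0.0104; sum 1820.4 to 1969 CPM in CKO and 1487 to 1665 CPM in FLOX), among them the chaperones Hspa9 (0.70) and Hspd1 (0.54). Camera called this list in 4 alternatives: without a filter (adjusted p = 0.0327), without CKO replicate 2 (0.0387), without FLOX replicate 3 (0.0331), and without CKO replicate 2 and FLOX replicate 6 together (0.037). Of 25 genes of the tricarboxylic acid cycle 4 rose and 6 fell, also when adjusted over the list alone (median -0.02, camera adjusted p = 0.864), with Idh3a at 0.40. The counted annotation held 0 genes of the mitochondrial chromosome, so transcripts encoded by mitochondrial DNA were not analysed here.

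Some inflammatory genes rose and fewer fell. Of 26 tested genes of classical activation 10 rose and 5 fell (12 and 6 adjusted over the list alone; median 0.13). Against other genes the list was not called (camera adjusted p = 0.325), while fry, which tests the list by itself, called it higher (adjusted p = 0.000312), and its sum was higher in all CKO libraries (889.9 to 1153 against 778 to 843 CPM). The chemokine Ccl2 rose from 63.8 ± 7.29 to 348 ± 101 CPM (SD, n = 4 each, log2 fold change 2.45), on average by more than the whole sum. The sum therefore does not show a rise of the other members. Tnf rose by 1.04 and the inflammasome sensor Nlrp3 by 0.99 on the log2 scale. Nos2, Il6 and Il1b had 0 to 7 counts per library and were not tested. For 22 extracellular matrix genes 9 rose and 5 fell (9 and 6 adjusted over the list alone; median 0.20, camera adjusted p = 0.328, fry adjusted p = 0.000312 and higher), with Plau at 2.18 and Mmp13 at 1.37. For 27 antioxidant genes 8 rose and 7 fell, also when adjusted over the list alone (median 0.03, camera adjusted p = 0.757), with both subunits of the enzyme that starts glutathione synthesis higher (Gclm 1.18, Gclc 0.72). For 20 antigen presentation genes 6 rose and 7 fell (7 and 7 adjusted over the list alone; median -0.03, mean 0.02, camera pointing down, adjusted p = 0.93), with Tap1 at 0.90 and Psmb10 at -0.48. For 19 immediate early and handling stress genes 6 rose and 3 fell, also when adjusted over the list alone (median -0.06, mean 0.03, camera pointing up, adjusted p = 0.785), with Hsp90aa1 at 0.85. The sum of that list was higher in all CKO libraries (3299.9 to 3504 against 2601 to 2996 CPM). On average it rose by less than Hsp90aa1 (277.3 in FLOX to 498.6 CPM in CKO) and another heat shock gene (1537 to 1933 CPM) together. The sum therefore does not show a rise of the other members.

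**Figure D3:**
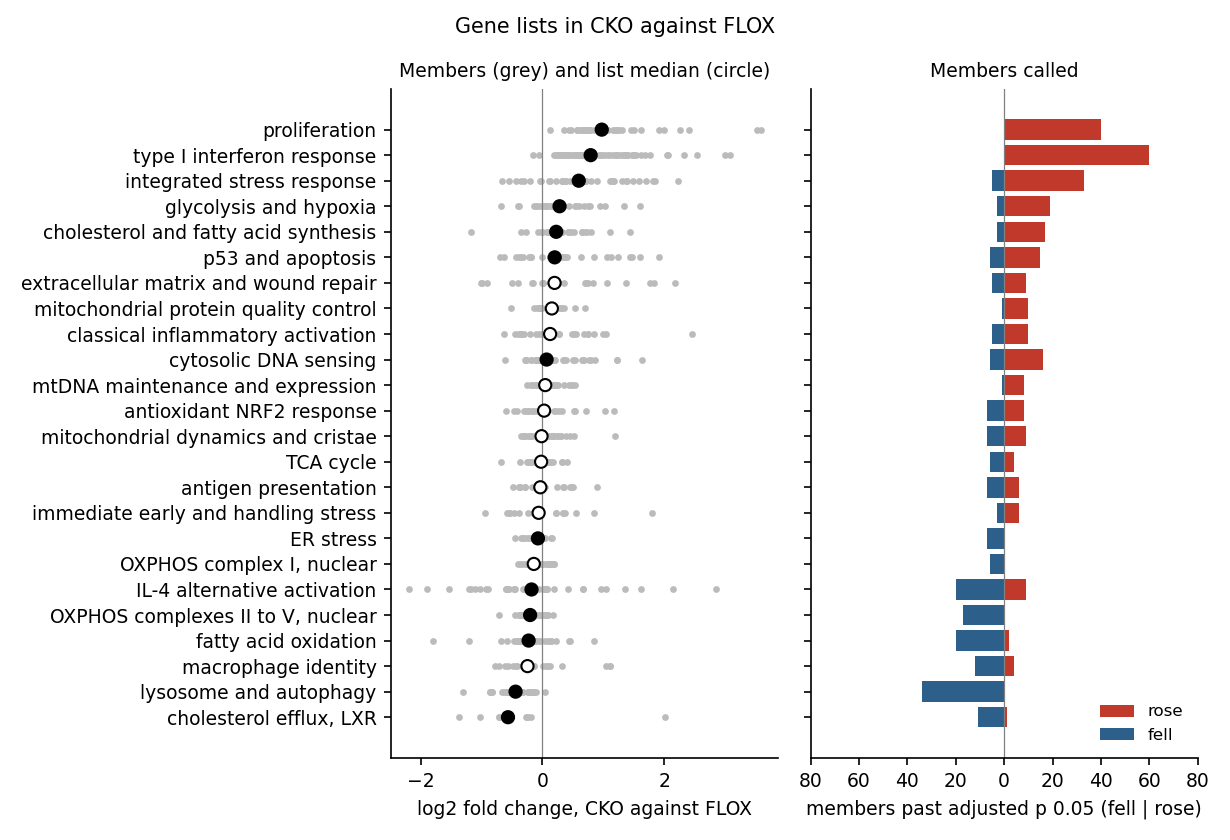
Left, log2 fold change (CKO against FLOX) of each tested member of 24 gene lists (grey) and the list median (circle, filled where the camera adjusted p with a preset correlation was under 0.05); right, the number of members that fell (blue) and rose (red). The proliferation (median 0.97) and interferon (0.79) lists lie highest and the cholesterol efflux (-0.57) and lysosome (-0.44) lists lowest.

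Among markers of other cell types, some rose and others fell. Of 6 tested neutrophil and precursor markers 4 rose and 1 fell (5 and 1 adjusted over the list alone; median 1.33, camera adjusted p = 0.185, fry adjusted p = 0.0162). S100a9 stood at 3.11 ± 1.26 CPM in CKO and 1.03 ± 0.285 in FLOX, Ngp at 1.22 ± 0.381 and 0.300 ± 0.138, and Ltf at 1.03 ± 0.223 and 0.312 ± 0.146, whereas Csf3r fell from 268 ± 40.3 to 129 ± 12 CPM (SD, n = 4 each). Of 4 tested monocyte markers 3 rose and 1 fell, also when adjusted over the list alone, with Ccr2 at 1.12 and S100a4 at -0.46. Of 6 dendritic cell markers 1 rose (Cd207, 2.28, or 2.87 without CKO replicate 2 and FLOX replicate 6 together) and none fell (camera adjusted p = 0.592, fry adjusted p = 0.00307). The list had a median log2 fold change of 0.14 and a mean of 0.47. Means over it thus rest largely on Cd207, at 5.30 CPM in CKO and 1.03 CPM in FLOX. Of 6 osteoclast markers 1 rose and 3 fell (median -0.13, mean 0.02, camera pointing down, adjusted p = 0.757), and of 5 stromal and endothelial markers 2 rose and 1 fell (median 0.15, mean -0.21, camera pointing up, adjusted p = 0.757). The stromal and endothelial marker that fell was Adipoq (-2.34), which gives that mean its sign. The lists of other granulocytes, of lymphocytes and of erythroid cells each had 2 tested genes; 1 rose and 1 fell in each of the first 2, and Car2 fell in the last (-1.44). Mean log2 CPM was higher in all CKO libraries for the dendritic markers (3.03 ± 0.08 against 2.56 ± 0.10) and lower in all for the erythroid ones (2.38 ± 0.26 against 3.08 ± 0.11, SD, n = 4 each). These means cover the tested genes alone, and the sums over all members overlapped (219.8 to 237 against 207.5 to 250.5 CPM for dendritic and 36.1 to 38.5 against 36.5 to 48.0 CPM for erythroid markers). Markers of pancreatic islets, included since the extraction protocol in the labels names islets, summed to 7 to 17 counts per library. The 4 tested Y-linked genes were expressed in every library, and 1 of them fell (1 adjusted over the list alone).

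Dmpk and its neighbour Dmwd rose side by side on chromosome 7. Dmwd (ENSMUSG00000030410, chromosome 7, 19076227 to 19082776, plus strand, mm10), named here after its values were seen, had 83 to 133 counts per CKO library and 0 to 4 per FLOX library (log2 fold change 5.99, 95% interval 5.27 to 6.72, edgeR). Dmpk (ENSMUSG00000030409, 19083849 to 19093821, plus strand), the protein kinase gene whose repeat expansion causes myotonic dystrophy, starts 1072 bp downstream and had 162 to 310 counts per CKO library and 4 to 41 per FLOX library (log2 fold change 4.02, 95% interval 3.17 to 4.88). Each size moved by more than 1.5 times when 1 FLOX library was left out: without FLOX replicate 3 Dmwd had a log2 fold change of 6.75, and without FLOX replicate 6 Dmpk had one of 4.83. With the replicate number as a block Dmpk was at 3.82 and was not called (edgeR adjusted p = 0.104). The 22 other tested genes within 500 kb had a median log2 fold change of -0.07 and a range from -0.40 to 0.71, and 6 of them were called. Sympk, the nearest tested gene upstream, changed by 0.30 and Fbxo46, the nearest downstream, by -0.16 (edgeR adjusted p = 0.207). Between Sympk and Dmwd lies Rsph6a with 0 counts in every library, which allows up to 3 counts per library by counting error alone, and Six5 beyond Dmpk had 1 to 5 counts.

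**Figure D4:**
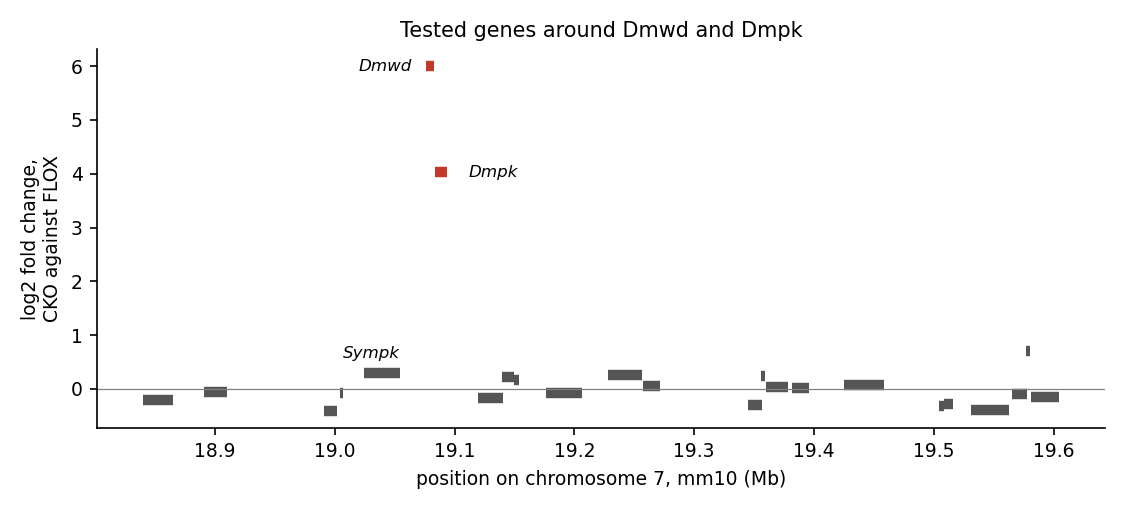
Log2 fold change (CKO against FLOX) of the tested genes around Dmwd and Dmpk against their position on chromosome 7 (Mb, mm10); each bar spans a gene. Dmwd (5.99) and Dmpk (4.02) stand apart from the 22 others, which lie between -0.40 and 0.71.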

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

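The tests on Opa1 and Lyz2, on Dmwd and Dmpk and on the interferon and proliferation lists were chosen after these results were seen; the splits of the libraries were planned before.

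Of 236 groups of 4 libraries examined (113 genes the text names and 5 library measures, in each genotype), 22 held a library whose distance from the others passed Dixon's 95% criterion, where chance flags about 1 in 20, or 11.8. CKO replicate 2 was the library apart in 14 of them, other CKO libraries in 6 and FLOX libraries in 2. CKO replicate 2 was highest in CKO for Slc6a12 (25.8 CPM), Tfeb (52.6), Pltp (366), Sdha (353), Gpnmb (5037), Csf1r (2014) and for the share of counts in the 20 most abundant genes (11.1%). It was lowest for Cdh1 (33.0 CPM), Hspd1 (238), Mtfr2 (32.9), Atad3a (26.99), Gclm (70.2), Plau (56.1) and Id3 (22.9). CKO replicate 6 was apart for Ctsk (8.77 CPM, lowest), Tnf (13.3, highest) and Tfam (36.3, highest), CKO replicate 7 for Pkdcc (2.16, highest) and Pfkl (42.7, highest), and CKO replicate 8 for Slc2a1 (55.7, highest). In FLOX, replicate 6 was highest for Mcm2 (37.1 CPM) and replicate 7 for Gclc (33.9 CPM).

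Chance division of the libraries is argued against for the count of changed genes. Of the 35 splits into 4 and 4, only 1, the real one, gave as many as 5231. The highest of the others gave 0 by edgeR's adjusted p (1846 genes at an unadjusted p under 0.05, against 6030 in the real split). Chance is not excluded, since 35 splits cannot give a share below 1 in 35. Every other split mixes the groups that the first principal component parted, and a batch that follows the groups would give the same count. For the 13 lists called the margin was narrow. The real split again was the 1 of 35 with as many, but another split called 12 lists and the median of the others was 8, with 0 the lowest. The splits that called 12 kept 3 libraries of a genotype together, so they largely follow it. Among splits balanced for genotype, CKO replicates 2 and 7 with FLOX replicates 3 and 4 called 9. CKO replicates 2 and 6 with FLOX replicates 4 and 6 called 0. The preset correlation of 0.01 thus also called lists on some divisions that do not follow genotype. Of the 13 lists, 5 had their smallest camera p of all splits in the real one: type I interferon, proliferation, integrated stress response, lysosome and autophagy, and cholesterol efflux.

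Opa1 near the FLOX level with Lyz2 far below it in CKO was the first pattern weighed. Exchanged labels are argued against, since the highest CKO library had 0.346 times the Lyz2 CPM of the lowest FLOX library. Loss of 1 of 2 Lyz2 alleles to the Cre insertion alone is argued against too, since the upper 95% bound of Lyz2 in CKO was 32.1% of FLOX. A recombined transcript that is still counted, or recombination in only part of the cells, may account for the Opa1 total, whose lower 95% bound was 77.3% of FLOX, but the cases cannot be told apart because gene totals do not resolve exons. An insertion on both alleles and an effect of OPA1 loss on Lyz2 stay open, as untested.

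Dmwd and Dmpk, with 0 to 41 counts per FLOX library and 83 to 310 per CKO library, were the second pattern. A change of the whole region is argued against by the median log2 fold change of -0.0657 over the 22 other tested genes within 500 kb. A variant or a passenger segment carried by the CKO mice could produce such a local change; the lowest CKO library had 6.13 times the Dmpk CPM of the highest FLOX library, but genotype and any linked or background segment coincide in this design and cannot be told apart. Regulation through OPA1 loss stays open as the biological explanation, as untested.

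The rise of the interferon and proliferation lists was the third pattern. Trends on GC content and transcript length are argued against as its cause, since the medians after their removal were 0.79 and 0.94. Once the 20 most abundant genes were removed the medians were 0.81 and 0.99. That removal could hardly lower them, since both fits were TMM-scaled, which already limits the pull of abundant genes. A few abundant genes taking the counts are argued against by their share, 9.88% to 11.1% in CKO and 12.6% to 13.7% in FLOX, too small a difference for such medians. A lower share of macrophages in CKO may contribute and cannot be told apart: 0 of 8 marker lists of other cell types lay apart in all libraries the same way by mean log2 CPM and by summed CPM. By mean the neutrophil, monocyte and dendritic lists were higher and the erythroid list of 2 tested genes lower (dendritic and erythroid sums overlapped), and by sum the neutrophil, monocyte and basophil, mast cell and eosinophil lists were lower, as was that of macrophage identity (13386 to 15521 against 18213 to 19349 CPM). More cells of another type, or more dividing precursors, stay open beside the genotype, and several of these markers are also expressed by macrophages.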

How the results depend on the processing

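Added after the data were seen were the offset for GC content and length, the share of pairs in no gene as a covariate, and leaving out CKO replicate 2 and FLOX replicate 6 together. Of 113 named and tested genes 108 kept direction and side of the threshold in all alternatives that gave a value (Lyz2 was itself among the 20 genes removed and has 19); 3 fell out of the call in at least 1 (Tfam, Dmpk, Sympk), 2 entered it (Opa1, Mrc1) and 0 reversed. The cause of changes was not tested unless named. Between 4857 and 6127 genes were called by the settings other than single libraries left out, the replicate block and the fold threshold, and 4273 to 5210 with each library left out. No scaling moved the median log2 fold change by more than 0.1 or the split of higher and lower calls by more than 10 points. Each of these scalings assumes that most genes do not change. A stable median and split were thus largely set in advance, and that assumption was not tested. A log2 fold change above 1 left 673 genes by construction (538 higher, 135 lower). The term for sex and the removal of mitochondrially encoded genes were not run. Depth limits genes of a few counts per library, such as Nos2, Il6, Il1b, Ifnb1 and Rsph6a.

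With the replicate block 3503 genes were called, 1985 higher and 1518 lower. Numbers 6 and 7 alone occur in both groups, so that fit rests on 2 pairs and 1 residual degree of freedom, fewer than the 6 of the comparison without it, which by construction lowers its power. The deviations of the same-numbered libraries had correlations of 0.14 (number 6) and -0.07 (number 7), and no label says that numbers pair libraries. There Dmpk had a log2 fold change of 3.82 and was not called (adjusted p = 0.104, against 1.89e-10 to 0.104 over its 20 alternatives).

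Opa1 passed the threshold with upper-quartile factors (-0.18), the GC offset (-0.24), the GC and length offset (-0.24) and without FLOX replicate 3 or 6; with each library left out it ran from -0.23 to -0.12.
Tfam passed in 10 of 20 alternatives and lost the call without CKO replicate 6 (adjusted p = 0.0781) or 8 (0.0504) and without FLOX replicate 3 (0.0722), 4 (0.1) or 6 (0.0607); Mrc1 entered it in 7, among them without CKO replicate 2 (0.0282) and FLOX replicate 7 (0.0197). Sympk lost it with the replicate block (0.0939).

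For gene lists the values are camera adjusted p unless fry is named. With an estimated correlation 0 lists were called, 0 higher and 0 lower: 0.292 for interferon, 0.318 for glycolysis, integrated stress response, cholesterol efflux, proliferation, p53 and lysosome, 0.35 for ER stress, 0.545 for DNA sensing and fatty acid oxidation, 0.626 for IL-4 and cholesterol and fatty acid synthesis, and 0.654 for complexes II to V. Fry called 17 lists, 13 of them higher. It passed for inflammatory and matrix genes (0.000312 each), dendritic (0.00307) and neutrophil markers (0.0162), mitochondrial protein quality control (0.0104) and mitochondrial DNA maintenance (0.0245), missed for IL-4 (0.0624) and complexes II to V (0.113), and turned the direction of the tricarboxylic acid cycle (0.986) and antigen presentation (0.604). Apart from the estimated correlation, 10 of the 28 lists had the same direction and side of the threshold in every alternative that gave a list test (DESeq2 gave none).

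Upper-quartile factors ended the calls of DNA sensing and ER stress (0.0568 each), and limma-voom that of DNA sensing (0.0515). Without a filter complex I and mitochondrial protein quality control (0.0327 each), macrophage identity (0.0399) and neutrophil markers (0.0358) passed and antigen presentation turned (0.993). The replicate block ended ER stress (0.108) and p53 (0.063), called macrophage identity (0.0369) and turned immediate early genes (0.302). Removal of the 20 most abundant genes ended ER stress (0.0549) and turned antigen presentation (0.964). The GC offset ended IL-4 (0.0573) and DNA sensing (0.0555) and turned antigen presentation (0.874); with length the values were 0.0695, 0.05 and 0.806. The share of pairs in no gene ended IL-4 (0.0998) and DNA sensing (0.102), called complex I (4.07e-05) and macrophage identity (0.026), and turned mitochondrial dynamics (0.937) and the antioxidant list (0.608). Without CKO replicate 2 and FLOX replicate 6 together, DNA sensing (0.0709) and ER stress (0.0903) ended, mitochondrial protein quality control (0.037) and macrophage identity (0.0282) passed, and the tricarboxylic acid cycle turned (0.936).

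With each library left out in turn, adjusted p ran from 0.0103 to 0.063 for IL-4 (lost without CKO replicate 2 or 6 or FLOX replicate 4 or 7), 0.0331 to 0.0855 for DNA sensing (lost without CKO replicate 2, 6 or 7 or FLOX replicate 4, 6 or 7), 0.0297 to 0.0911 for ER stress (lost without CKO replicate 2, 6 or 7 or FLOX replicate 3 or 6), 0.00293 to 0.411 for complex I (passed without FLOX replicate 4 or 7), 0.0331 to 0.181 for mitochondrial protein quality control (passed without CKO replicate 2 or FLOX replicate 3) and 0.0219 to 0.102 for macrophage identity (passed without CKO replicate 2). Directions turned within 0.628 to 0.998 for the tricarboxylic acid cycle, 0.489 to 0.998 for antigen presentation, 0.431 to 0.963 for the antioxidant list and 0.597 to 0.92 for immediate early genes. The cause of these changes was not tested.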

Other observations

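The gene groups below were chosen after the values were seen, so their adjusted p-values (camera over 7 such groups, preset correlation) do not count as independent evidence. Most tested genes that report activity of the ERK pathway rose. Of a 10-gene activity signature that includes Ccnd1, Etv5, Epha2, Dusp6 and Spry2, 7 were tested, 6 rose and 1 did not pass. The median log2 fold change was 2.92 (camera adjusted p = 2e-05, adjusted p = 0.145 with an estimated correlation). The member that did not pass was among the more abundant (225.2 CPM in FLOX, 233.7 in CKO, log2 fold change 0.05, edgeR adjusted p = 0.72). Epha2, an ephrin receptor, had 1 to 3 counts per FLOX library and 52 to 114 per CKO library (log2 fold change 5.74, edgeR). The phosphatase gene Dusp6 rose from 3.35 ± 0.904 to 25.5 ± 6.66 CPM and Spry2 from 1.68 ± 0.542 to 5.61 ± 1.51 CPM (SD, n = 4 each); both encode feedback inhibitors of that pathway. Targets of BMP and SMAD signalling rose as well, 6 of 6 tested (median 1.54, camera adjusted p = 0.000568, adjusted p = 0.145 with an estimated correlation), with Id1, Smad6 (3.22) and Id3 (2.32) in front. The FLOX levels of Id1, Epha2 and Smad6 lie below 1 CPM, where a log2 fold change is imprecise.

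Subunits of the vacuolar ATPase, the proton pump that acidifies lysosomes, fell with the lysosome genes: 13 of 17 tested fell and none rose (median -0.36, camera adjusted p = 2.99e-06, adjusted p = 0.145 with an estimated correlation), with Atp6v0d2 the lowest. Chemokines went both ways, with 7 of 17 rising and 6 falling (median 0.07, camera adjusted p = 0.966): Ccl2 rose by 2.45 on the log2 scale and Ccl8 fell by 2.77. Of 77 cytosolic ribosomal protein genes 10 fell and none rose (median -0.15, camera adjusted p = 0.000734, adjusted p = 0.978 with an estimated correlation). The share that fell was smaller than over all tested genes (2492 of 11519). Of 77 mitochondrial ribosomal protein genes 11 rose and 7 fell (camera adjusted p = 0.341), and of 38 proteasome genes 9 rose and 4 fell (camera adjusted p = 0.145). The median of each of the 7 groups kept its sign under 5 other scalings. These were RLE and upper-quartile factors, the 20 most abundant genes removed, and the offsets for GC content and for GC content and length. Over them the median of the cytosolic ribosomal genes ran from -0.15 to -0.07 and that of the vacuolar ATPase from -0.36 to -0.31. All 5 assume that most genes do not change, so they do not test that assumption.

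The division of FLOX libraries on the second principal component ran along transcript length. Across genes, the loading on that component had a Spearman rho of -0.63 with transcript length and 0.34 with GC content; genes are not independent replicates, and no p is given. FLOX replicates 4 and 7 had 9.41% and 9.60% of read pairs in no gene, against 7.67% and 7.02% in FLOX replicates 3 and 6. The log2 fold change between genotypes had a rho of 0.06 with length and -0.10 with GC content.

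The monocyte gene Ly6c2 was not tested, being too low, yet had 10 to 21 counts in every CKO library and 2 to 4 in every FLOX library. It does not stand for its list, since the sum of the 9 monocyte markers was lower in every CKO library (983.66 to 1119.8 against 1190.5 to 1588.6 CPM).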
